A study of Mus musculus with 14 samples.

How the data were processed

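Total RNA from mouse bone marrow progenitors and from cultured cells was measured on 14 Affymetrix mouse expression arrays. Per the labels' protocols, small amounts of RNA were amplified to cDNA and labelled with biotin before hybridisation. The deposited values are probe-set intensities made by the authors with RMA, per the submitters' processing notes. The version of RMA, its software and whether all arrays were normalized together are not given in the sources used here. RMA corrects the background, normalizes between arrays and summarises the probes of a set into 1 value. The intensities are on a linear scale, with array medians between 31.16 and 32.98, so log2 was taken before any test and no further scaling was applied. The 27 probe sets for bacterial control transcripts, which mouse RNA does not contain, had a median intensity of 7.35 and reached 27.8, so intensities in that range are close to background. The highest control of each array, between 20.8 and 27.8, was taken as its floor, a choice made after the data had been seen. A gene at or below the floor on every array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the mean floor of the dimmer group's arrays, on the log2 scale, and no fold is given where both groups lay below it. In the averaged comparison this was done where the dimmer group lay below the floor in 1 or more populations, and the floor stood in on each array below it. Where 1 of the 2 arrays of a group lay above the floor, the fold is as fitted: Fcer1a (averaged), Mttp, Pgr, Cd14 and Ms4a2 in WT LSK, Meis1 in WT GMP, Cd79a in WT CMP, and S100a9, Cd79b and Gbp2 in replated cells. With that array raised to its floor these folds were up to 1.31 times smaller. For Fcer1a in LSK the fold was 1.88 times smaller, so the value with the floor is given. Tests, list medians and tests of differences between populations used the values as measured. Between the arrays of a group, the Pearson correlation of log2 values across probe sets lay between 0.9719 and 0.9951. The number of arrays limits the precision. Slide and scan dates were not used here, so no batch was tested.

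The file holds 45101 probe sets. The platform annotation names 1 gene for 34958 of them and several genes for 932, and 9211 are not listed there. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, in which 34754 probe sets matched, 204 did not and 0 symbols changed. The table was used only for names and for which genes neighbour each other. A gene was represented by its probe set with the highest mean over all arrays, which left 18194 genes, of which 9012 had several probe sets. Named genes past the threshold had 369 other probe sets, counted once per comparison, of which 89 lay below the floor in every group compared; of the rest 227 moved the same way at unadjusted p < 0.05, 51 did not pass and 2 (of Iglv1 in KO LSK and of Gnas in replated cells) moved the other way. For 652 genes the chosen probe set is of the type that can hybridise with related transcripts. Probe sets naming several genes or none were left out of gene-level tests, and their positions in the transcripts were not analysed here.

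Arrays were grouped by their titles into 7 groups of 2. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with data.table, version 1.17.8) in 1 linear model with a mean per group over all 14 arrays, so that all comparisons share an estimate of the spread with 7 residual and 2.19 prior degrees of freedom. Benjamini-Hochberg adjustment was applied over the 18194 genes of each comparison, and an adjusted p below 0.05 counted as passing. Errors of log2 differences are the moderated standard errors (SE) of limma. A fold is 2 raised to the log2 difference, and a group's level is the mean of its log2 values turned back to intensity, except for the Tet2 probe sets, given as the mean and SD of the intensities themselves. Tests were two-sided. The model, the threshold, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except those said to be added later.

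Named genes were, per comparison, Tet2, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between the groups (in each population for the averaged comparison), up to 4 members with the smallest p of each list (2, as values, where none passed), and Meis1, Mecom, Hoxa9, Cebpa, Cebpd, Mpo, Csf1, Csf1r, Kit, Flt3, Tet1, Tet3 and Dnmt3a. Symbols that are clone names were left out. Genes named outside this rule are said to have been chosen after their values were seen.

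A set of 19 gene lists was tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The lists were stem cell and self-renewal genes, the Hoxa cluster, lymphoid priming, erythroid, megakaryocyte, myeloid regulators, primary granules, late neutrophil, monocyte and macrophage, MHC class II, mast cell and basophil, B, T and NK cell, cell cycle, interferon, DNA methylation, immediate early, imprinted, p53 target and sex-linked genes. The same tests were repeated with the correlation estimated from the data. They were also repeated with fry, whose directional p tests whether a list moves, on balance, one way and whose mixed p tests change in either direction. Neither compares the list with other genes. In 17 of the 152 tests the median, the mean and the direction of the test differed in sign, and 0 of these 17 passed the threshold.

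The procedure was tested on simulated data drawn for the 18194 genes, with 200 of them changed by known folds. The simulated noise was normal and independent, with the same spread in all groups for a gene. The shares below hold under that assumption, and groups that differ in spread were not simulated. In the simulated average over populations, 39% of genes changed 1.5-fold, 70.3% of those changed 2-fold and 91.5% of those changed 4-fold were recovered with 7 false calls. For a single population the recovery of 2-fold changes was 35.4% in LSK, 33.3% in CMP and 26.9% in GMP, and that of 4-fold changes was 64.2%, 65.6% and 63.3%, with 11, 0 and 5 false calls.

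Alternatives were median centring, cyclic loess, the mean of all probe sets of a gene, all probe sets, genes above the median mean level, a trended robust prior, array weights, the 12 sorted arrays alone, the groups compared alone, the replicate number as a block, other thresholds and leaving out each array. Counts without genes of the X and Y chromosomes, counts also without genes of the chromosome that carries Tet2, and the mast cell list against WT LSK were added after the data had been seen.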

Results

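Gene expression was measured in progenitors sorted from the bone marrow of wild-type (WT) mice and of littermates in which Tet2 had been deleted (KO). Tet2 is an enzyme that oxidises methylated cytosine in DNA. Deletion was induced by pIC injection in mice carrying Mx, on a mixed B6/129 background. LSK cells are lineage-negative cells with c-Kit and Sca1 on their surface, a population that includes the blood stem cells. CMP and GMP lack Sca1, carry CD34 and are told apart by low (CMP) or high (GMP) Fc gamma receptor. They are the common myeloid and the granulocyte-macrophage progenitors. The labels put the sort of LSK and CMP at 4 weeks after deletion and give no time for GMP. A further KO group came from CD150-positive LSK cells replated 5 times in culture, and no replated WT group was analysed here. Each of the 7 groups had 2 arrays. Nothing in the labels says that the arrays of a group came from separate animals, so each p measures only the spread between these samples. The first principal component held 48.6% of the variance and set the replated arrays apart from the sorted ones.

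Tet2 itself was measured by 2 probe sets, whose place relative to the deleted part of the gene is not known here, so they do not check the genotype labels. At the brighter probe set, intensities in LSK were 641 ± 265 (SD, n = 2) in WT and 1360 ± 710 in KO. They were 1260 ± 44.3 and 1980 ± 48.5 in CMP, 1620 ± 594 and 2300 ± 105 in GMP, and 1800 ± 26.1 in replated KO cells. At the dimmer one they were 74.3 ± 11.8 and 52.1 ± 49.6 in LSK (WT before KO), 89.3 ± 4.06 and 63.4 ± 25.7 in CMP, 162 ± 67.1 and 144 ± 44.2 in GMP, and 788 ± 11.3 in replated KO cells. Averaged over the 3 populations, the KO minus WT log2 difference in a limma fit of all probe sets was 0.75 ± 0.23 (SE, adjusted p = 0.341) at the brighter and -0.54 ± 0.38 (adjusted p = 0.737) at the dimmer probe set. The dimmer probe set rose in replated cells against KO LSK by 4.35 ± 0.66 (adjusted p = 0.00154) and against KO GMP by 2.49 ± 0.66 (adjusted p = 0.0272).

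Genes that report the sex of the donor separated the genotypes. Xist, the RNA that silences an X chromosome in female cells, was at intensities of 26.3, 28.1 and 21.3 in WT LSK, CMP and GMP and at 6590, 6080 and 5010 in the KO counterparts. The Y-linked translation factor gene Eif2s3y was at 894, 1130 and 1160 in WT and at 7.29, 11.2 and 9.15 in KO, where it lay in the range of the bacterial controls. Replated KO cells resembled WT in this respect, with Xist at 20.1 and Eif2s3y at 2070 (n = 2 arrays for each value). Every KO minus WT difference below therefore goes together with a difference in sex-linked expression.

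**Figure D1:**
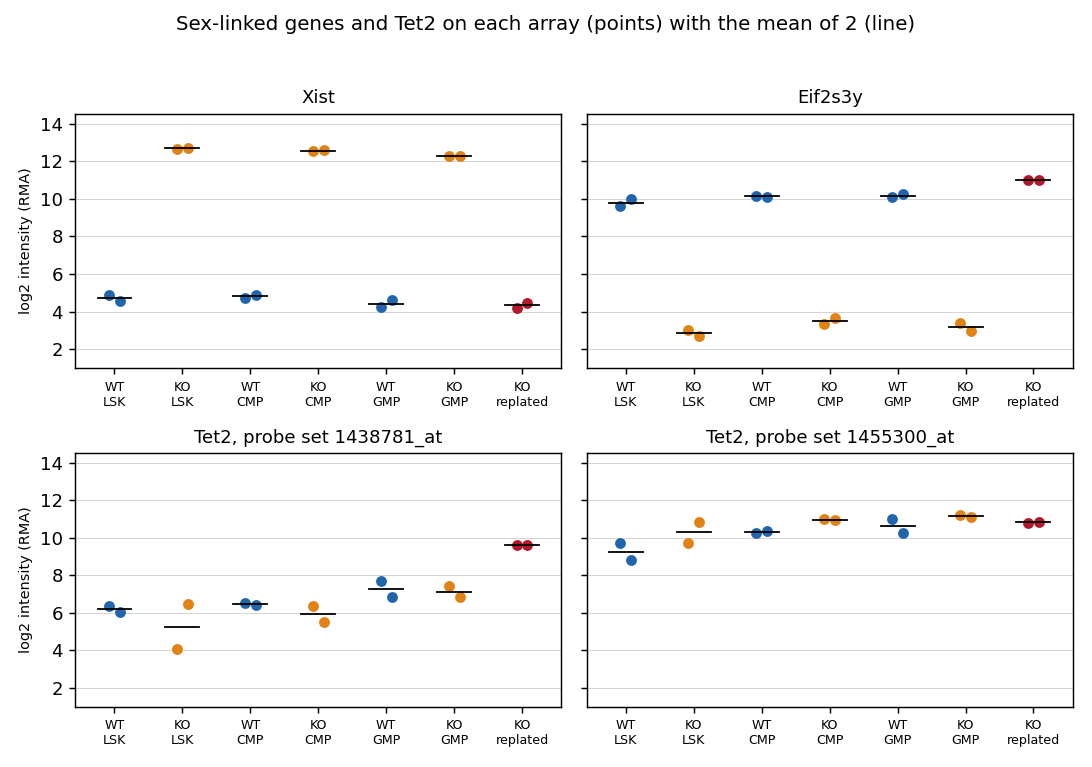
Log2 RMA intensity (vertical axis) of sex-linked genes and of the Tet2 probe sets in each group (horizontal axis), with each array as a point and the mean of 2 arrays as a line, in blue for WT, orange for sorted KO and red for replated KO. Xist was high in the sorted KO arrays (6590 in LSK) and low in the WT (26.3 in LSK) and replated arrays (20.1).

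The first question was what Tet2 loss changed in sorted progenitors, and the comparison averaged over LSK, CMP and GMP set 6 KO arrays against 6 WT arrays. Gbp2b, a member of the interferon-inducible guanylate-binding proteins, rose at least 13.9-fold (adjusted p = 2.05e-08), and Ifi44l, an interferon-stimulated gene, at least 11.7-fold (adjusted p = 1.09e-07), since both lay within the range of the bacterial controls in WT. Neither is on the interferon list, of which 0 of 33 genes passed limma's threshold and 2 rose adjusted over the list alone (camera adjusted p = 0.421). Fcer1a, which encodes the alpha chain of the high-affinity IgE receptor, rose 9.48-fold (log2 difference 3.25 ± 0.31 SE, adjusted p = 0.0021). Ccr1, a chemokine receptor, rose at least 6.76-fold, and the B cell surface gene Ms4a1 at least 3.08-fold. Sh3d19 was at least 9.49-fold lower in KO (adjusted p = 0.00221) and the inhibitory receptor gene Btla at least 7.43-fold lower, with 4 and 3 of the 6 KO arrays in the range of the controls. Lamtor3, part of a complex that anchors signalling to lysosomes, fell by 1.71 on the log2 scale (SE 0.09, adjusted p = 1.16e-05). In all, limma called 56 of 18194 genes, 29 higher and 27 lower in KO. Without genes of the X and Y chromosomes 51 remained, and 40 remained without those and the genes of the chromosome that carries Tet2. Both counts were added after the data had been seen.

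Of the lists, MHC class II genes, which present antigen to T cells, moved up, with 1 of 9 members past the threshold (Cd74, 3.57-fold, adjusted p = 0.049) and 4 risen when adjusted over the list alone (camera adjusted p = 3.09e-05; adjusted p = 0.166 with an estimated correlation). Monocyte and macrophage genes also moved up, with 1 of 26 past the threshold (Cd14, 2.08-fold, adjusted p = 0.0407) and 4 risen adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.166 with an estimated correlation). Primary granule genes, which encode the enzymes of early granulocytes, moved down slightly, with a median log2 difference of -0.09, 0 of 18 past limma's threshold and 2 fallen adjusted over the list alone (adjusted p = 0.00319; adjusted p = 0.108 with an estimated correlation). Myeloid regulators had a median of -0.09, with 1 of 22 fallen adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.132 with an estimated correlation). Lymphoid priming genes had a median of -0.21, with 2 of 20 risen and 3 fallen adjusted over the list alone (adjusted p = 0.0309; adjusted p = 0.277 with an estimated correlation). Cell cycle genes had a median of -0.04 with 0 of 33 members past limma's threshold, also adjusted over the list alone (adjusted p = 0.0355; adjusted p = 0.351 with an estimated correlation). The 4 sex-linked genes all changed, 1 up and 3 down, and this call held with an estimated correlation (adjusted p = 3.1e-06 and 0.0381). The other 12 lists had adjusted p between 0.052 and 0.931. Among them 2 of 20 mast cell and basophil genes rose (Fcer1a and Cd200r3, the latter within the range of the controls on 11 of the 12 arrays). So did 1 of 22 DNA methylation genes (Apobec3, a cytidine deaminase that restricts retroviruses, 2.02-fold) and 1 of 19 megakaryocyte genes (Selp, the adhesion molecule P-selectin, 3.74-fold).

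No gene among those followed in every comparison passed in this average. The log2 differences were 0.69 ± 0.46 for Meis1, 1.04 ± 0.37 for Mecom, -0.21 ± 0.12 for Hoxa9, -0.12 ± 0.08 for Cebpa, -0.18 ± 0.25 for Cebpd, 0.03 ± 0.06 for Mpo, 0.14 ± 0.16 for Csf1, 0.07 ± 0.43 for Csf1r, -0.01 ± 0.11 for Kit, -0.29 ± 0.16 for Flt3, -0.14 ± 0.26 for Tet1, 0.36 ± 0.26 for Tet3 and 0.03 ± 0.16 for Dnmt3a (SE), with adjusted p between 0.419 and 0.982. A fit of the 12 sorted arrays alone called 27 genes, all of them among the 56. The count also became 27 without either replated array. It was 91 without WT LSK replicate 1, 122 without WT LSK replicate 2, 100 without KO LSK replicate 1, and 126 without KO LSK replicate 2. It was 36 without WT CMP replicate 2, 89 without KO CMP replicate 1, 37 without WT GMP replicate 2, 35 without KO GMP replicate 1 and 30 without KO GMP replicate 2. Of 22 named genes that passed, 18 also passed without each array in turn, whereas Cd74 and Cd14 each did not pass without 10 of the 14 arrays, Cd200r3 without 9 and Fam83e (-1.65, adjusted p = 0.049) without 12. The list call for lymphoid priming genes ended without replicate 1 of WT LSK, KO LSK, WT CMP, WT GMP or KO GMP, or replicate 2 of KO CMP (adjusted p up to 0.185). That for myeloid regulators ended without replicate 1 of WT LSK or WT GMP, or replicate 2 of KO GMP (up to 0.137). That for monocyte and macrophage genes ended without replicate 1 of WT LSK, either KO LSK array, or replicate 2 of WT GMP or KO GMP (up to 0.136). That for cell cycle genes ended without either WT LSK array, replicate 2 of KO LSK or KO CMP, or replicate 1 of WT CMP, WT GMP or KO GMP (up to 0.241). Without WT LSK replicate 1 the number of lists past the threshold fell from 7 to 4.

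**Figure D2:**
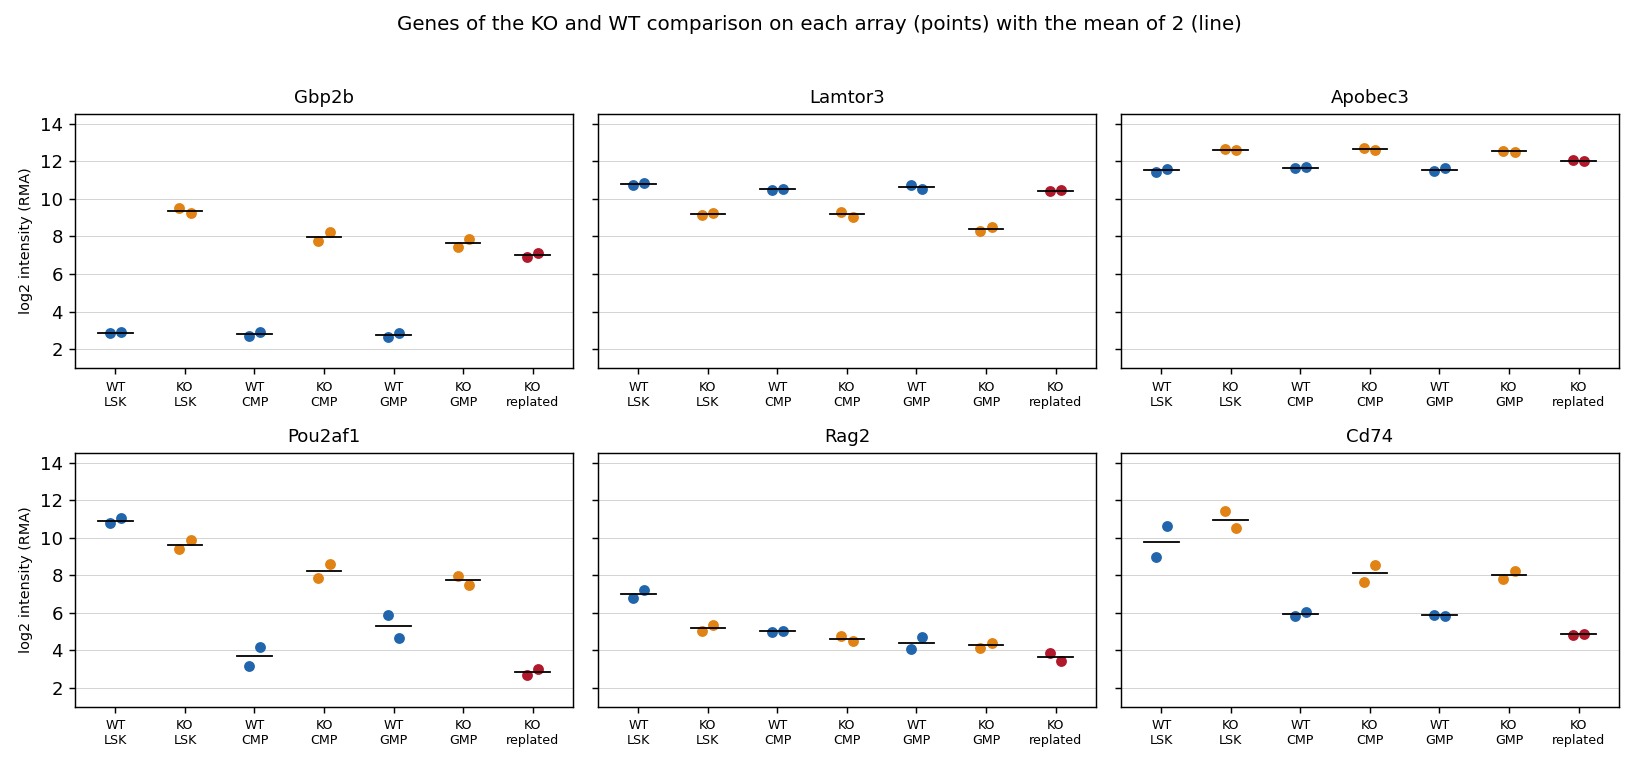
Log2 RMA intensity (vertical axis) of genes that changed between KO and WT in each group (horizontal axis), with each array as a point, the mean of 2 arrays as a line, and blue for WT, orange for sorted KO and red for replated KO. Gbp2b lay at 7.29 in WT LSK and 664 in KO LSK, and Lamtor3 at 1760 and 589.

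In LSK cells, 2 of 20 lymphoid priming genes fell in KO. Rag2, part of the recombinase that assembles antigen receptor genes, fell by 1.82 on the log2 scale (SE 0.26, adjusted p = 0.0337), from an intensity of 129 to 36.4, and Il12a fell by 1.46 (SE 0.23, adjusted p = 0.0486). Adjusted over the list alone 5 fell, and the list had a median log2 difference of -0.68 (camera adjusted p = 1.16e-07; adjusted p = 0.0531 with an estimated correlation). The immunoglobulin light chain segment Igkv14-111 fell by 3.11. Among B, T and NK cell genes, Ms4a1 rose at least 8.25-fold (adjusted p = 0.00136) while 2 rose and 3 fell adjusted over the list alone, and the list as a whole had an adjusted p of 0.808. Fcer1a rose at least 6.05-fold to an intensity of 142 (adjusted p = 0.0424), with 1 of 2 WT arrays in the range of the controls. Selp rose 4.17-fold. Changes in 3 further genes rested on 1 probe set each: the progesterone receptor gene Pgr rose 10.6-fold, the lipid transfer protein gene Mttp 18.3-fold, and the imprinted noncoding RNA Rian was at least 4.22-fold lower. The other Mttp probe set had a log2 difference of 0.28, and those of Pgr (-0.06 and 0.35) and Rian (-0.27, 0.29 and -0.03) lay within the range of the controls in both groups.

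A total of 48 genes passed in LSK, 24 in each direction. The Pearson correlation between the 2 arrays of a group was lowest in KO LSK (0.9719) and WT LSK (0.9755), and 0.9951 in replated cells. All comparisons share 1 estimate of the spread, which may therefore be too small for LSK. The 4 sex-linked genes moved as in the average (adjusted p = 0.00015; adjusted p = 0.0531 with an estimated correlation), and the other 17 lists had adjusted p between 0.12 and 0.808. Of the followed genes, Meis1 (0.54 ± 0.80), Mecom (0.22 ± 0.64), Hoxa9 (0.24 ± 0.21), Mpo (0.15 ± 0.11) and Flt3 (-0.79 ± 0.28) did not pass. In a fit of the 4 LSK arrays alone, limma called 0 genes, with 948 at an unadjusted p below 0.05. The count became 125 without WT LSK replicate 1, 232 without WT LSK replicate 2, 142 without KO LSK replicate 1 and 249 without KO LSK replicate 2. It was 26 without either WT CMP array, 29 without either KO GMP array and 23 without either replated array. Of 20 named genes that passed, 11 also passed without each array in turn; Rag2 did not pass without 8 of the 14 arrays, Il12a without 13, Fcer1a without 12, Mttp without 10, Rian without 9, Pgr without 8 and Selp without 3 (adjusted p up to 0.07 for Rag2 and 0.108 for Il12a). Both list calls held without each array, and the number of lists past the threshold rose from 2 to 5 without WT LSK replicate 2 or KO LSK replicate 2 and to 4 without KO LSK replicate 1.

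In CMP, primary granule genes had slightly lower values in KO. Of 18 primary granule genes, 0 passed limma's threshold singly or adjusted over the list alone, but only 2 had a positive difference and the median was -0.15 (camera adjusted p = 5.32e-05; adjusted p = 0.0315 with an estimated correlation). Within it Gstm1 had -0.41 ± 0.12 and Ly86 -0.80 ± 0.31. Myeloid regulators had a median of -0.28 with 6 of 22 above 0 and 0 past limma's threshold, also adjusted over the list alone (adjusted p = 0.00237; adjusted p = 0.0416 with an estimated correlation). Irf8, a monocyte and dendritic cell transcription factor, had -0.54 ± 0.19. Late neutrophil genes had a median of 0.26, with 10 of 17 above 0 and 0 past limma's threshold, also adjusted over the list alone (adjusted p = 0.511). All 9 MHC class II genes had higher values in KO, with 3 risen adjusted over the list alone and 0 past limma's threshold over all genes (adjusted p = 5.32e-05; adjusted p = 0.189 with an estimated correlation). H2-Eb1 had 2.72 ± 0.55 and Cd74 2.19 ± 0.51, with Cd74 at an intensity of 60.4 in WT and 276 in KO. Among single genes, Pou2af1, a coactivator of B cells, rose at least 12.3-fold (adjusted p = 0.00558) to an intensity of 301. Fcer1a rose 17.5-fold from 44.7 to 783 (adjusted p = 0.0233), Ccr1 rose 11.1-fold and Ms4a1 at least 2.16-fold. B, T and NK cell genes as a list had a median of 0.14, or 0.04 with values under the floor set to it (camera adjusted p = 0.636). Of these 20 genes 1 rose, and adjusted over the list alone 1 rose and 2 fell.

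A total of 22 genes passed in CMP, 13 higher and 9 lower. Wdfy1 fell by 3.45 (SE 0.24, adjusted p = 0.000419), with other probe sets at -2.18, -4.17, -0.04 and 0.30. The adhesion receptor gene Adgrl2 had a log2 difference of -1.87 (adjusted p = 0.0186), and Arhgap31 had -1.96 (adjusted p = 0.0139), a fall that none of its other probe sets had (0.61, 0.17 and 0.22). Cell cycle genes had a median of -0.11 with 0 of 33 past limma's threshold, also adjusted over the list alone (adjusted p = 0.00237; adjusted p = 0.189 with an estimated correlation). The sex-linked list passed in both forms (adjusted p = 9.52e-06 and 0.0315), and the other 14 lists had adjusted p between 0.0539 and 0.881. In a fit of the 4 CMP arrays alone, 2 genes passed. The count became 14 without WT CMP replicate 2 and 66 without KO CMP replicate 1; it was also 14 without genes of X, Y and the chromosome of Tet2. Of 17 named genes that passed, 9 also passed without each array in turn; Fcer1a did not pass without 8 of the 14 arrays, Adgrl2 without 6, Apobec3 without 4, Ms4a1, Ifi202b and Lamtor3 without 3 each and Arhgap31 without 2. The cell cycle call ended without WT CMP replicate 1 (adjusted p = 0.158) or KO CMP replicate 2 (adjusted p = 0.173).

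In GMP, Ifi202b, an interferon-inducible gene, rose at least 30.5-fold (adjusted p = 5.54e-05) and Gbp2b at least 8.55-fold. The interferon list, which holds neither, had 0 of 33 genes past limma's threshold, also adjusted over the list alone (adjusted p = 0.467). Ccr1 rose 16.3-fold (adjusted p = 0.000145) and Selp 4.41-fold. Lamtor3 fell by 2.24 (SE 0.15, adjusted p = 0.000169). MHC class II genes again had higher values, with 8 of 9 above 0, 1 risen adjusted over the list alone and 0 past limma's threshold over all genes (adjusted p = 0.00609; adjusted p = 0.435 with an estimated correlation). Monocyte and macrophage genes had a median of 0.26, with 0 of 26 past limma's threshold, also adjusted over the list alone (adjusted p = 0.0169; adjusted p = 0.225 with an estimated correlation). Cd14 had 0.91 ± 0.28 and Fn1 0.81 ± 0.29. Of B, T and NK cell genes 1 of 20 rose adjusted over the list alone (Ms4a1, at 12.9 in WT and 38.1 in KO, adjusted p over all genes 0.206). Of mast cell and basophil genes 1 passed, Cd200r3, at intensities in the range of the controls in 3 of 4 arrays (2 risen and 1 fallen adjusted over the list alone).

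Of all genes, 17 passed in GMP, 10 higher and 7 lower. The sex-linked list passed in both forms (adjusted p = 2.33e-06 and 0.0361), and the other 16 lists had adjusted p between 0.127 and 0.874. Hoxa9 had -0.76 ± 0.21 (adjusted p = 0.786) and Mecom 1.73 ± 0.64 (adjusted p = 1). In a fit of the 4 GMP arrays alone, 6 genes passed, and 10 of the 17 calls lay outside X, Y and the chromosome of Tet2. Without WT GMP replicate 1 the count became 30. Of 15 named genes that passed, 10 also passed without each array in turn; Selp did not pass without 11 of the 14 arrays, Apobec3 without 8, and Cd200r3 and Wdfy1 without 2 each. The MHC class II call ended without WT GMP replicate 1 (adjusted p = 0.12) or KO GMP replicate 2 (adjusted p = 0.206), and the monocyte and macrophage call without WT GMP replicate 2 (adjusted p = 0.341) or KO GMP replicate 2 (adjusted p = 0.11).

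The comparisons in the 3 populations share no array, although they share the estimate of spread, and 12 genes passed in all of them. Xist, Gbp2b, Ifi44l, Ifi202b and Apobec3 were among the 7 that rose in all, and Eif2s3y, Kdm5d, Uty, Lamtor3 and Wdfy1 were the 5 that fell in all. LSK and CMP shared 9 risen genes, against 0.0171 for independent lists of these sizes, LSK and GMP shared 8 against 0.0132, and CMP and GMP shared 8 against 0.00715. Shared falls numbered 6, 5 and 5, against 0.0119, 0.00923 and 0.00346. Of the 12 genes, Xist, Eif2s3y, Kdm5d and Uty are sex-linked, and Gbp2b, Ifi44l and Lamtor3 lie on the chromosome that carries Tet2. Whether the 3 populations came from different animals is not known here, so shared calls may reflect the same donors. Across genes, which are not independent replicates, the Pearson correlation of the KO minus WT differences was 0.193 between LSK and CMP, 0.195 between LSK and GMP and 0.254 between CMP and GMP (Spearman 0.099, 0.088 and 0.115). Without X and Y genes the Pearson values were 0.163, 0.159 and 0.218.

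Few differences between populations in the KO effect passed a test of the difference itself. Ifi44l rose at least 41.9-fold in LSK, 15.2-fold in CMP and 2.48-fold in GMP. The fitted difference between GMP and LSK passed (-4.49 ± 0.36, adjusted p = 0.00844), and Ifi44l was the 1 gene past the moderated F-test over the populations (limma adjusted p = 0.0288; 1027 genes at an unadjusted p below 0.05). Pou2af1 had -1.28 ± 0.46 in LSK against its rise in CMP, and the fitted difference between them passed (5.83 ± 0.65, adjusted p = 0.0353), as it did for 3 other genes, Mzb1, Ecscr and Trgv1 (the last 2 named after their values were seen). Lymphoid priming genes as a list differed between LSK and CMP, with a median difference of effects of 0.79, 0 of 20 past limma's threshold and 8 risen adjusted over the list alone (adjusted p = 1.43e-06; adjusted p = 0.0835 with an estimated correlation). Between LSK and GMP their median was 1.07 with 0 of 20 past limma's threshold and 6 risen adjusted over the list alone (adjusted p = 3.85e-09 and 0.0338 with an estimated correlation). Erythroid genes differed between LSK and CMP with a median of -0.47, 0 of 26 past limma's threshold, also adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.251 with an estimated correlation). Between GMP and CMP effects limma called 0 genes, with 679 at an unadjusted p below 0.05, and 0 of 19 lists, whose adjusted p was 0.084 or higher. The F-test count was 25 without WT LSK replicate 1, 48 without WT LSK replicate 2, 25 without KO LSK replicate 1 and 47 without KO LSK replicate 2. It was 4 without WT CMP replicate 1, 11 without KO CMP replicate 1, 12 without KO CMP replicate 2 and 11 without WT GMP replicate 1. It was 0 without WT CMP replicate 2, WT GMP replicate 2, either KO GMP array or either replated array, where 859 to 984 genes had an unadjusted p below 0.05.

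Within WT, CMP were compared with LSK to describe the sorted populations without Tet2 loss. Lymphoid genes were far lower in CMP. Jchain, the joining chain of secreted antibodies, went from an intensity of 6540 to 14.9, at least 268-fold lower (adjusted p = 0.00643), Pou2af1 was at least 78.7-fold lower (adjusted p = 0.000214) and Rag1 at least 42.4-fold lower. Of 20 lymphoid priming genes 9 fell, and 13 adjusted over the list alone (camera adjusted p = 2.94e-19 and 0.00238 with an estimated correlation). In the same direction, 3 of 20 B, T and NK cell genes fell (5 adjusted over the list alone; Igll1 by 5.91 and Cd79a by 3.10; adjusted p = 5.24e-06; adjusted p = 0.0543 with an estimated correlation). So did 3 of 9 MHC class II genes (6 adjusted over the list alone; Cd74 by 3.88; adjusted p = 1.4e-07; adjusted p = 0.0543 with an estimated correlation). The B, T and NK cell list had a median of -0.582, or -0.065 with values under the floor set to it. Of its 20 genes, 8 lay in the range of the controls in both groups. Stem cell genes fell in 7 of 35 cases and 15 adjusted over the list alone, with Procr, a surface marker of stem cells, down by 3.31 and Esam by 2.76 (adjusted p = 3.94e-10 and 0.00292 with an estimated correlation). Primary granule genes rose in 9 of 18 cases and 10 adjusted over the list alone, with the neutrophil proteases Ctsg up 2.86-fold and Elane up 2.25-fold (adjusted p = 3.29e-11 and 0.00238 with an estimated correlation). Mpo, myeloperoxidase, rose 1.56-fold. Interferon genes fell in 4 of 33 cases and 9 adjusted over the list alone, with Iigp1 at least 25.9-fold lower (adjusted p = 1.06e-08; adjusted p = 0.0562 with an estimated correlation).

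In all, limma called 278 genes, 88 higher and 190 lower in CMP, and 15 of 19 lists passed. Of the 278 genes, 3 lay in the range of the controls in both groups. Myeloid regulators rose in 3 of 22 cases and 7 adjusted over the list alone, with Irf8 up 3.43-fold, while 1 fell adjusted over the list alone (adjusted p = 0.00548; adjusted p = 0.0543 with an estimated correlation). Monocyte and macrophage genes rose in 5 of 26, also adjusted over the list alone (F13a1 6.46-fold, Ccr2 6.34-fold; adjusted p = 0.00641; adjusted p = 0.0543 with an estimated correlation). Mast cell and basophil genes rose in 4 of 20 and 5 adjusted over the list alone (Ms4a2 10.3-fold, Cpa3 4.23-fold; adjusted p = 0.0136; adjusted p = 0.0543 with an estimated correlation). Erythroid and megakaryocyte lists also moved up, each with 1 risen member (Mt1 3.08-fold, with another probe set at 0.06, and Pf4 2.29-fold; 5 and 4 risen and 1 each fallen adjusted over the list alone; adjusted p = 0.0136 and 0.0155; adjusted p = 0.12 and 0.0543 with an estimated correlation). So did cell cycle genes, with 29 of 33 above 0 and 0 past limma's threshold, also adjusted over the list alone (adjusted p = 0.000478; adjusted p = 0.0562 with an estimated correlation). Immediate early (0 of 23 past limma's threshold, 2 fallen adjusted over the list alone), imprinted (1 of 23 fallen, Rian, at least 3.72-fold at 1 probe set, also adjusted over the list alone) and late neutrophil genes moved down, the last with 1 of 17 risen (Il1b, 1.9-fold; 2 risen adjusted over the list alone), at adjusted p of 0.00823, 0.00823 and 0.0412 (adjusted p = 0.321, 0.0543 and 0.476 with an estimated correlation). In that form 3 of the 15 lists passed. The imprinted list had a median of -0.108, or -0.019 with values under the floor set to it, and 8 of its 23 genes lay in the range of the controls in both groups. The Hoxa cluster, DNA methylation, p53 target and sex-linked lists had adjusted p of 0.0752, 0.709, 0.728 and 0.938. In a fit of the 4 arrays alone, 13 genes passed. The count became 534 without WT LSK replicate 2, 118 without WT CMP replicate 1 and 87 without WT CMP replicate 2. Of 51 named genes that passed, 18 also passed without each array in turn, among them Jchain, Pou2af1, Rag1, Igll1, Irf8 and F13a1. Others did not: Procr, Ctsg, Elane, Cd74 and Rian did not pass without 2 of the 14 arrays, Esam, Mpo, Iigp1, Cpa3 and Pf4 without 3, Il1b without 7 and Ms4a2 without 10 (adjusted p up to 0.215). The erythroid call ended without WT LSK replicate 1 (adjusted p = 0.0733) and that for myeloid regulators without WT LSK replicate 2 (adjusted p = 0.0778). The immediate early call ended without WT LSK replicate 1 (adjusted p = 0.373) or WT CMP replicate 2 (adjusted p = 0.06), and the late neutrophil call without those (adjusted p = 0.606 and 0.634) or either WT GMP array (adjusted p = 0.0587).

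From WT CMP to WT GMP, primary granule genes rose further. Of 18 members all had positive differences, 5 rose and 12 rose adjusted over the list alone, with Elane up 2.77-fold (log2 difference 1.47 ± 0.16, adjusted p = 0.00516) and Gstm1 4.21-fold (camera adjusted p = 2.32e-16 and 0.00129 with an estimated correlation). Fcgr3, an Fc gamma receptor of the kind used in the sort, rose 7.13-fold (adjusted p = 0.00104) as the 1 of 22 myeloid regulators past the threshold (4 adjusted over the list alone; adjusted p = 0.000614 and 0.0163 with an estimated correlation). Stem cell genes fell in 4 of 35 cases and 11 adjusted over the list alone, with the growth regulator Hmga2 down by 2.21 and the transcription factor Gata2 by 0.78 (adjusted p = 2.11e-11 and 0.0019 with an estimated correlation). Lymphoid priming genes fell in 4 of 20 cases and 10 adjusted over the list alone, with 1 risen there, Dntt down by 4.27 and the cytokine receptor Flt3 by 2.41 (adjusted p = 1.14e-10 and 0.00642 with an estimated correlation). Megakaryocyte genes fell in 3 of 19 cases and 8 adjusted over the list alone, with Selp down by 2.09 (adjusted p = 7.03e-11 and 0.00144 with an estimated correlation). Late neutrophil genes had 2 of 17 risen, Pglyrp1 5.18-fold and Anxa1 1.83-fold (another Anxa1 probe set had -0.28), and mast cell and basophil genes 1 risen, Cma1 at least 2.34-fold, and 1 fallen, Gata2; neither list passed (adjusted p = 0.888 for both).

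In all, limma called 162 genes, 78 higher and 84 lower in GMP. Prom1, a membrane glycoprotein, rose 52-fold. MHC class II genes (0 of 9 past limma's threshold, 1 fallen adjusted over the list alone) and interferon genes (0 of 33 past limma's threshold, also adjusted over the list alone) moved down at adjusted p of 0.0474 and 0.0321, with adjusted p = 0.475 and adjusted p = 0.513 with an estimated correlation. The other 12 lists had adjusted p between 0.0565 and 0.888. In a fit of the 4 arrays alone, limma called 0 genes, with 2059 at an unadjusted p below 0.05. The count became 65 without WT CMP replicate 1, 37 without WT CMP replicate 2, 46 without WT GMP replicate 2 and 100 without either replated array. Of 37 named genes that passed, 6 also passed without each array in turn: Prom1, Vcam1, Clec4a2, Fcgr3, Gstm1 and Cma1. Of the others, Elane did not pass without 1 array, Dntt, Flt3 and Pglyrp1 without 2, Selp without 3, Anxa1 without 4, Gata2 without 6 and Hmga2 without 8 (adjusted p up to 0.241). The MHC class II call ended without any 1 of the LSK or WT CMP arrays or WT GMP replicate 1 (adjusted p up to 0.226), and the interferon call without WT CMP replicate 1 (adjusted p = 0.146) or WT GMP replicate 1 (adjusted p = 0.175).

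**Figure D3:**
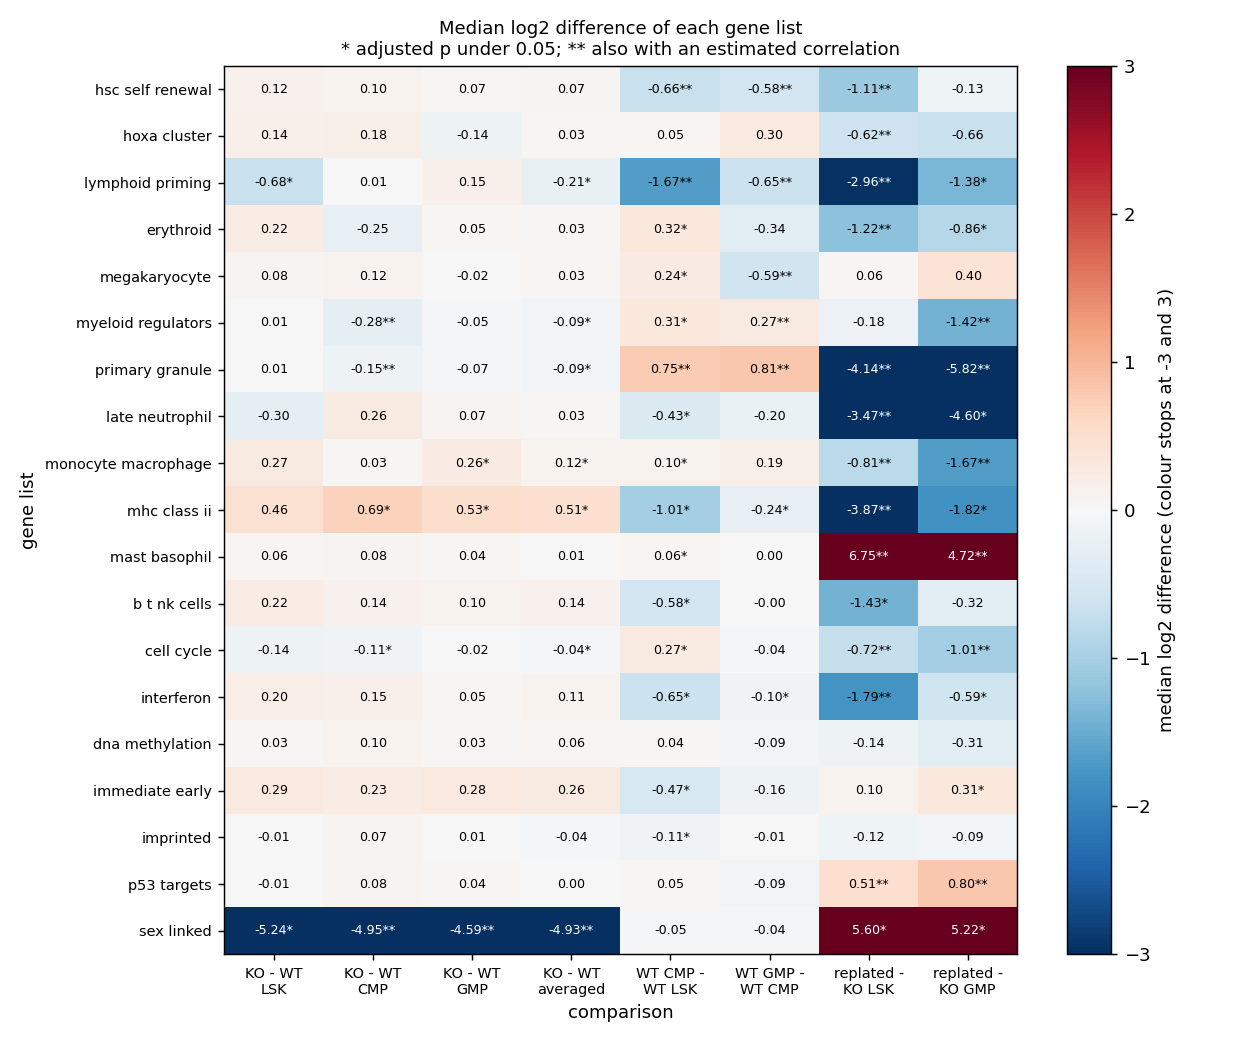
Median log2 difference of each gene list (vertical axis) in each comparison (horizontal axis), coloured from blue for lower to red for higher with the colour scale ending at 3 in both directions, with 1 star for a camera adjusted p below 0.05 and 2 stars where the estimated correlation also gave an adjusted p below 0.05. The mast cell and basophil list stood at 6.75 in replated KO cells against KO LSK and the primary granule list at -4.14.

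Replated KO cells, started from CD150-positive LSK cells, were compared with the sorted KO LSK arrays. Genes of mast cells reached very high levels in the replated cells. Cma1, mast cell chymase, went from an intensity of 15.6 to 15400, a rise of at least 716-fold (adjusted p = 1.21e-09). Mcpt4, another mast cell protease, rose at least 172-fold to 3700, and Tph1, the enzyme that starts serotonin synthesis, at least 501-fold to 10800. Of 20 mast cell and basophil genes 18 rose, and 19 adjusted over the list alone, with a median of 6.75, or 5.72 with each value under the highest control of its array set to that control (camera adjusted p = 1.96e-20 and 0.000303 with an estimated correlation). Among granulocyte genes, Mpo was at least 344-fold lower (adjusted p = 3.08e-10), from 7480 to 14.1, in the range of the bacterial controls, and S100a9 fell by 8.42. Primary granule genes fell in 14 of 18 cases, also adjusted over the list alone, while 2 rose (3 adjusted over the list alone; adjusted p = 4.12e-10 and 0.00377 with an estimated correlation). Late neutrophil genes fell in 12 of 17 and 14 adjusted over the list alone (adjusted p = 1.29e-10 and 0.0426 with an estimated correlation). Hoxa9, a homeobox gene of stem and progenitor cells, was at least 73.4-fold lower, from 1600 to 6.06, and Cebpa, the master regulator of granulocytes, fell by 5.83. Kit, the receptor for stem cell factor, rose 2.29-fold (adjusted p = 0.00135).

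Lymphoid priming genes fell in 15 of 20 cases, also adjusted over the list alone (Mef2c by 6.82; adjusted p = 6.05e-11 and 0.00736 with an estimated correlation). MHC class II genes fell in 8 of 9, also adjusted over the list alone (Cd74 by 6.10; adjusted p = 1.46e-07 and 0.0426 with an estimated correlation). B, T and NK cell genes fell in 9 of 20, also adjusted over the list alone (Cd79b by 4.99; adjusted p = 8.78e-05; adjusted p = 0.0688 with an estimated correlation). Interferon genes fell in 22 of 33 and 26 adjusted over the list alone (Gbp2 by 4.86; adjusted p = 6.05e-11 and 0.0426 with an estimated correlation). Cell cycle genes fell in 19 of 33, also adjusted over the list alone, with the replication helicase gene Mcm7 down by 2.03 (adjusted p = 1.2e-08 and 0.0222 with an estimated correlation). The p53 target genes rose in 9 of 22 with 1 fallen, also adjusted over the list alone, with the cell cycle inhibitor Cdkn1a up 13.3-fold (adjusted p = 0.00129 and 0.024 with an estimated correlation). Stem cell genes fell in 18 of 35 and rose in 6 (19 and 6 adjusted over the list alone; Hlf down by 6.71, Sult1a1 up 38.2-fold; adjusted p = 9.79e-05 and 0.024 with an estimated correlation). Monocyte and macrophage genes fell in 12 of 26 and rose in 3 (13 and 3 adjusted over the list alone; Ms4a6c at least 76.3-fold lower, the chemokine Ccl2 up 54.7-fold; adjusted p = 0.00336 and 0.0426 with an estimated correlation). Erythroid genes fell in 11 of 26 and rose in 3 (14 and 3 adjusted over the list alone; Car1 down by 6.77; adjusted p = 0.000483 and 0.0426 with an estimated correlation). Hoxa genes fell in 3 of 9 (5 adjusted over the list alone; adjusted p = 0.00998 and 0.0426 with an estimated correlation). The sex-linked genes moved the other way from the sorted KO cells, with Eif2s3y at least 96.1-fold higher and Xist at least 303-fold lower (adjusted p = 0.0169; adjusted p = 0.0768 with an estimated correlation). Among DNA methylation genes (9 of 22 fallen, 5 risen; 9 and 6 adjusted over the list alone; adjusted p = 0.21), Tet1 fell by 4.40 and Dnmt3b, a DNA methyltransferase, by 3.89, while Dnmt3a had -0.52 ± 0.28. Megakaryocyte, myeloid regulator, immediate early and imprinted lists had adjusted p of 0.939, 0.138, 0.382 and 0.202. The megakaryocyte list had a median of 0.06 but a mean of -0.38, with 8 of 19 members risen and 8 fallen. Between replated cells and KO LSK, 4559 genes passed, 1969 higher and 2590 lower, and the count became 2937 without replated replicate 2. Of 86 named genes that passed, 84 also passed without each array in turn. Of the 4559 genes, 96 lay in the range of the controls in both groups. Culture, the sort and the sex-linked genes all differ between these groups.

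**Figure D4:**
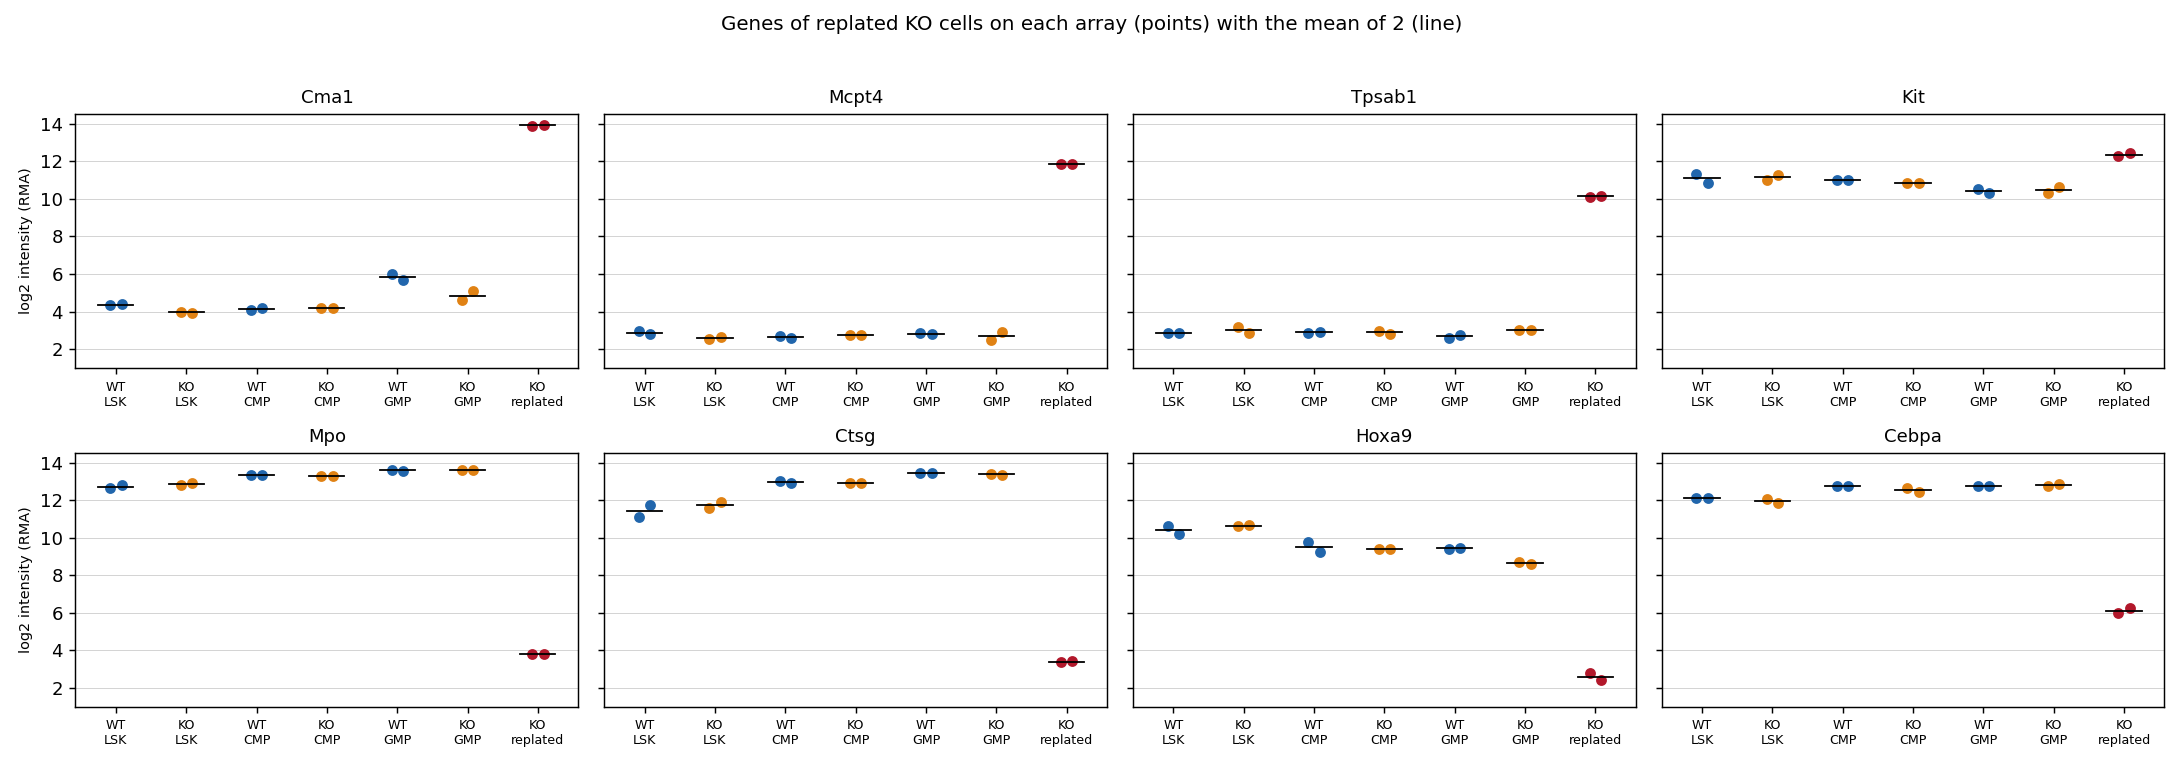
Log2 RMA intensity (vertical axis) of mast cell, granulocyte and regulator genes in each group (horizontal axis), with each array as a point, the mean of 2 arrays as a line, and blue for WT, orange for sorted KO and red for replated KO. Cma1 stood at 15400 in replated cells and at 57.2 or below in the sorted groups, and Mpo at 14.1 against 6750 or more.

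Replated cells were also compared with KO GMP. Tph1 rose at least 422-fold (adjusted p = 4.04e-09) and Mcpt4 at least 145-fold. Of 20 mast cell and basophil genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 2.59e-17 and 0.000528 with an estimated correlation). The fallen one was Mcpt8, a basophil protease (-0.93 ± 0.25, adjusted p = 0.0212, named after its value was seen). Ctsg was at least 491-fold lower (adjusted p = 1.94e-09), Mpo at least 568-fold lower and Csf1r, the receptor that drives macrophage growth, at least 113-fold lower. Primary granule genes fell in 15 of 18 cases with 1 risen, also adjusted over the list alone (adjusted p = 2.83e-16 and 0.000699 with an estimated correlation). Monocyte and macrophage genes fell in 16 of 26 with 3 risen, also adjusted over the list alone (adjusted p = 7.69e-05 and 0.0177 with an estimated correlation). Myeloid regulators fell in 12 of 22 with 2 risen (13 and 3 adjusted over the list alone; Irf8 at least 106-fold lower; adjusted p = 0.000802 and 0.0177 with an estimated correlation). Kit rose 3.68-fold, Mecom 5.99-fold (adjusted p = 0.0145) and Meis1 5.74-fold (adjusted p = 0.0451), so that Mecom stood at 2970 in replated cells and 497 in KO GMP. Other Meis1 probe sets had 0.52 and 0.48.

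Cell cycle genes fell in 23 of 33 cases and 27 adjusted over the list alone (the DNA repair enzyme Ung by 2.88; adjusted p = 5.82e-11 and 0.0136 with an estimated correlation). The p53 target genes rose in 10 of 22 with 1 fallen, also adjusted over the list alone (Zmat3 29.3-fold, Cdkn1a 12.7-fold; adjusted p = 0.000275 and 0.0169 with an estimated correlation). Late neutrophil genes fell in 12 of 17 (14 adjusted over the list alone; adjusted p = 6.67e-11; adjusted p = 0.0604 with an estimated correlation). Erythroid genes fell in 11 of 26 with 1 risen (13 and 2 adjusted over the list alone; adjusted p = 0.000275; adjusted p = 0.0521 with an estimated correlation). Lymphoid priming genes fell in 10 of 20 with 3 risen, also adjusted over the list alone (adjusted p = 0.00319; adjusted p = 0.0885 with an estimated correlation). MHC class II genes fell in 5 of 9 (7 adjusted over the list alone; adjusted p = 0.00251; adjusted p = 0.191 with an estimated correlation). Interferon genes fell in 12 of 33 with 2 risen (13 and 2 adjusted over the list alone; adjusted p = 0.00736; adjusted p = 0.323 with an estimated correlation). Immediate early genes rose in 7 of 23 with 1 fallen, also adjusted over the list alone (Klf2 12.2-fold; adjusted p = 0.00631; adjusted p = 0.323 with an estimated correlation). Sex-linked genes rose in 3 of 4 cases with Xist fallen (adjusted p = 0.012; adjusted p = 0.0885 with an estimated correlation). The stem cell, Hoxa, megakaryocyte, B, T and NK cell, DNA methylation and imprinted lists had adjusted p of 0.452, 0.0642, 0.135, 0.194, 0.452 and 0.795. Against KO GMP 4612 genes passed, 1850 higher and 2762 lower, and 70 of the 4612 lay in the range of the controls in both groups. Of 85 named genes that passed, 81 also passed without each array in turn; Meis1 did not pass without 12 of the 14 arrays and Mecom without 4. The immediate early call ended without KO GMP replicate 2 (adjusted p = 0.0667).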

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

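The tests of single arrays on the wrong side, of the loss of Tet2 itself behind the sex-linked genes, of the odds ratio for the chromosome of Tet2, of a shift of all values, of a difference in sex behind the mast cell list, of the loss of Tet2 without culture and of replated WT cells were chosen only after the results had been seen, as were the counts without whole chromosomes. The mast cell list against WT LSK was added after the sex-linked genes had been seen, but as a test of donors before its own value was. The other tests were chosen before.

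The KO effect differed between populations by a test of the difference for 5 genes. Between CMP and LSK the difference of effects was 5.83 ± 0.65 for Pou2af1 (SE; value 5.833; effects -1.28 in LSK, 4.56 in CMP and 2.45 in GMP), 3.31 ± 0.33 for Mzb1 (value 3.308; effects -2.32, 0.99 and 0.38), 2.64 ± 0.28 for Trgv1 (value 2.643; effects -1.78, 0.86 and -0.10) and 1.56 ± 0.17 for Ecscr (value 1.556; effects -0.73, 0.83 and 0.04), each at limma adjusted p = 0.0353. Between GMP and LSK it was -4.49 ± 0.36 for Ifi44l (value -4.492; adjusted p = 0.00844). These are fitted values, and some rest on intensities within the range of the bacterial controls: Ifi44l in WT, Pou2af1 in WT CMP, Mzb1 in WT CMP and GMP, and Trgv1 in KO LSK and in CMP and GMP of both genotypes. Ecscr and Trgv1 were named after their values were seen. As lists, lymphoid priming genes differed by a median of 0.794 between CMP and LSK and of 1.07 between GMP and LSK, and erythroid genes by -0.471 between CMP and LSK. With an estimated correlation, the second of these 3 passed (adjusted p = 0.0338), and the others did not (0.0835 and 0.251). Among 9160 probe sets that the annotation does not list, controls left out, 23 passed in the averaged comparison, 42 in LSK, 7 in CMP and 8 in GMP. Whether they measure further transcripts or genes already called was not checked here.

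Sex-linked genes led the calls between KO and WT. A single mislabelled array was argued against, since 0 of 12 sorted arrays had Xist on the side of the other genotype. The loss of Tet2 itself was argued against by Eif2s3y, which stood at 2069 in the replated KO cells, against a mean of 1053 in the sorted WT arrays. On every sorted KO array Xist was high, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay in the range of the bacterial controls. The sorted WT arrays showed the reverse at the probe sets used. Female KO and male WT donors would give these values. A test set for a difference in sex did not decide: 6 X-linked genes that escape inactivation in females all had higher values in KO. They were chosen as a class, not by their values, and their median of 0.142 (SE 0.078) did not exceed the bound of 2 times its error. That error measures how far these genes differ from each other, so missing the bound does not argue against a difference in sex. Sex and genotype cannot be told apart in the sorted arrays, so autosomal genes that differ with sex may be among the 51 calls that lie outside X and Y.

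Autosomal calls were more frequent on the chromosome that carries Tet2, with 11 of 51 (21.6%) against 5.2% of the genes tested (odds ratio 5.02, two-sided Fisher exact p = 5.37e-05). Of the 11, 5 lay within 100 measured genes of Tet2, where an even spread of the 51 over all autosomal genes would put 0.59. That figure in part restates the excess on the chromosome. The 11 calls lay a median of 123 measured genes from Tet2, against 333 for all genes measured on that chromosome. A candidate explanation is DNA flanking the targeted allele that came from another strain, as the B6/129 label would allow; the odds ratio is the pattern itself and does not test it, so this stayed open. Levels in replated KO cells went both ways and decide nothing, since the culture differed too: Lamtor3 stood at 1390 (1590 in sorted WT, 487 in sorted KO), Mttp at 15.7 (25.6, 250), Ifi44l at 5.24 (5.97, 269), Fabp4, named after its values were seen, at 10.5 (11.9, 34.2), Sh3d19 at 13.7 (248, 12.7) and Gbp2b at 128 (6.97, 322). Sequence differences under single probe sets stayed open. Their test took the brighter other probe sets of called autosomal genes on all chromosomes, 18 of them from 11 genes. Of those genes, only Wls, Tspan2 (both named after their values were seen) and Adgrl2 lie on the chromosome of Tet2, so it says little about this pattern. In it 17 of 18 moved the same way, some by almost nothing. The median was 0.515 (SE 0.186) against 0.956 for the calls of these genes. That passed the bound for excluding sequence differences by less than the error. No biological explanation was tested for this pattern.

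Mast cell and basophil genes as a list were higher in the replated cells than in KO LSK and KO GMP; WT LSK was also compared, and the other sorted groups were not. A shift of all values could not be judged from the deposited array medians (31.16 to 32.98), since RMA normalizes between arrays. Such a shift would move every list alike, whereas the primary granule list had a median of -4.136 (SE over genes 0.789) and this one 6.752. Both list medians were known when this test was chosen, so it is no independent support. A difference in sex as the whole source was argued against, since the list stood 6.567 higher than in WT LSK, whose sex-linked genes resemble those of the replated cells; other differences between donors stayed open, because both comparisons cross donors. In sorted LSK the loss of Tet2 without culture did not come with such values. There the list differed between KO and WT by a median of 0.059 (SE over genes 0.209, camera adjusted p = 0.693), with 8 of 20 members in the range of the controls in both groups. LSK are sorted as lineage-negative cells with c-Kit and Sca1. Cells outside that sort were not measured in this comparison, so it cannot decide what the loss of Tet2 alone does in them. Whether these values in culture needed the loss of Tet2 stayed open, because 0 replated WT arrays were there to compare.

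Random spread between these arrays was argued against as the source of the averaged count of 56 genes. Among 100 of the 108 ways to split the 12 sorted arrays within populations, 1, the real one, gave as many genes. The highest of the others gave 16. Every other split puts KO and WT arrays on the same side, so any steady difference between the genotype groups favours the real one. The test does not separate genotype from sex, strain or other differences between donors. Nothing in the labels says that the arrays came from separate animals.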

How the results depend on the processing

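The counts without X and Y genes and those also without the chromosome of Tet2 were chosen only after the results had been seen, and the mast cell list against WT LSK after the sex-linked genes had been; the other alternatives were chosen before. With median centring 558 of 562 values of named genes kept their direction and side of the threshold, with cyclic loess 555, with array weights 546, with the mean of probe sets 532 and with only the groups compared 372 of 502. Leaving out 1 array at a time, 7273 of 7868 did and 0 were reversed; a lone remaining array was assumed to vary like the other groups. Of 152 list tests, 150 kept theirs with median centring, 137 with cyclic loess and 117 with an estimated correlation. No scaling moved the median of all genes by over 0.1.

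For values that moved the cause was not tested, except where fewer arrays or genes or another threshold were used. The 12 sorted arrays alone gave 23 genes in LSK (48 as reported), 27 averaged (56), 100 for WT GMP against CMP (162) and 0 in the limma F-test (1; 859 at unadjusted p < 0.05). Only the groups compared gave limma counts of 0 in LSK (948 unadjusted), 2 in CMP (22), 6 in GMP (17), 13 for WT CMP against LSK (278) and 0 for WT GMP against CMP (2059 unadjusted). An adjusted p under 0.10 gave 140 in LSK, 117 averaged, 495 for WT CMP against LSK, 253 for WT GMP against CMP and 10 in the F-test. All probe sets gave 80 in LSK and 0 in the F-test (2633 probe sets unadjusted); the mean of all probe sets gave 82 and 4. Array weights gave 19 in LSK and 261 for WT GMP against CMP. Genes above the median mean level gave 14 in LSK, 11 in GMP, 167 for WT CMP against LSK, 0 in the F-test (560 unadjusted) and a correlation of 0.304 between CMP and GMP effects (0.254). A trend and robust prior gave 7 in the F-test. Without X, Y and Tet2 chromosome genes 14 remained in CMP and 10 in GMP. Of 21 correlations between groups of the deviations of arrays with the same replicate number, 1 was above 0.1. With 2 arrays a group this cannot decide whether the numbers pair the samples, and the labels do not say. A replicate block gave 0 in the F-test (1060 unadjusted). It gave 52, 23, 21 and 53 genes in LSK, CMP, GMP and averaged, and 270, 142, 4441 and 4509 in the other comparisons.

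With an estimated correlation camera called 0 lists in LSK (2 as reported; 2 at unadjusted p < 0.05), 3 in CMP (5), 1 in GMP (3), 1 averaged (7), 3 for WT CMP against LSK (15) and 6 for replated cells against KO GMP (13). With fry the counts were 4 in LSK, 8 in CMP and 1 in GMP, and with fry mixed 11 in LSK, 8 in CMP, 15 averaged and 13 for WT GMP against CMP (7). Reversed were Gnas in replated cells against KO LSK with the mean of all probe sets (-0.182, adjusted p = 0.592; 0.738 as reported), and with fry the megakaryocyte list against KO LSK (adjusted p = 0.00115, down) and the imprinted list against KO GMP (adjusted p = 0.0403, down). Single arrays gave correlations of KO effects of 0.126, 0.129, 0.108 and 0.071 between LSK and CMP, 0.092, 0.062, 0.129 and 0.158 between LSK and GMP, and 0.204, 0.138, 0.142 and 0.136 between CMP and GMP.

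Without 1 array at a time the counts ranged from 23 to 249 in LSK, 14 to 66 in CMP, 14 to 30 in GMP, 27 to 126 averaged, 87 to 534 for WT CMP against LSK, 37 to 173 for WT GMP against CMP, 2937 to 4784 and 3077 to 4903 for replated cells against KO LSK and KO GMP, and 0 to 48 in the F-test, with the arrays behind the moves named in the report. List counts ranged from 2 to 5 in LSK, 5 to 6 in CMP, 2 to 3 in GMP, 4 to 7 averaged, 12 to 15 and 5 to 8 in WT, and 14 to 14 and 12 to 14 in replated cells. The KO minus WT value of Tet2 ranged at the dimmer probe set from -2.117 to 0.241 in LSK, -0.981 to -0.13 in CMP, -0.573 to 0.298 in GMP and -0.937 to -0.151 averaged, and at the brighter from 0.48 to 1.599, 0.619 to 0.691, 0.171 to 0.934 and 0.562 to 0.935.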

Other observations

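The test of position on the path from LSK to GMP was chosen before its result was seen, after the granule and myeloid regulator lists had been found lower in KO CMP. The hypothesis was that the KO CMP arrays may lie earlier on that path. The 586 genes higher in WT GMP than in WT LSK had a median KO minus WT difference in CMP of -0.08, with 40.1% above 0 (camera p = 0.0485 with an estimated correlation), and the 704 genes lower there had a median of 0.143, with 64.9% above 0 (p = 0.125). At the preset correlation the p were 5.5e-05 and 0.00284. Both medians had the predicted sign, and in 4 of 4 pairs of a KO with a WT array the lower set stood above the higher one, by 0.189 to 0.245. These pairs reuse the same arrays, so they are not independent. Genes of the granule and myeloid regulator lists were not left out of the sets, so the test may in part restate what prompted it. The test had been set on the estimated correlation, with which the second set missed its threshold, so the hypothesis stayed undecided.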
